A study of Mus musculus with 20 samples.

How the data were processed

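RNA was sequenced from the hippocampus of mice that lack a working Fmr1 gene (labelled KO) and of C57 mice (labelled WT), in both sexes. The labels give 20 libraries in 4 groups of 5: female WT, female KO, male WT and male KO. Per the labels' protocols, total RNA was extracted with TRIzol and 1.3 µg per sample entered a SMARTER mRNA-seq library kit. Groups and replicate numbers were taken from the sample titles. The genotype field of the labels calls the mutant animals a knockdown while the titles call them KO, and the titles' word is used here. No label says whether the 5 samples of a group came from separate animals, and p-values measure only the spread between these samples.

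The deposited values are FPKM (fragments scaled to transcript length and to the mapped fragments of a library) per gene, 1 column per library, per the file headers. The submitters' processing notes name FastQC, HISAT2 and StringTie without versions and the build mm10. The annotation release, the trimming and the strand setting are not given in the sources used here. Each table lists the same 13256 genes, all labelled protein-coding, with Ensembl gene identifiers. Of these identifiers, 13243 are in GENCODE M21, which was used for GC content and for which genes overlap. Chromosome, start and end are those of the deposited tables. A gene model that overlaps another on the same strand (3208 of the tested genes) can share reads with it, and so can near-identical copies, and how StringTie split such reads is not known here.

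FPKM are not counts, and values down to 2e-06 do not fall on whole-read steps, so the depth of each library is unknown and no counting interval or detection floor was computed. Total FPKM per library ran from 230631 to 244976, which is set by the unit and is not a depth. A listed 0 can be a failed estimate: 18 to 28 genes per library were at 0.

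Genes were kept when they reached 0.5 FPKM in at least 5 libraries, which left 13174. Values were taken as log2(FPKM + 1) and fitted with limma 3.58.1 (limma-trend, R 4.3.3) with a mean for each of the 4 groups over all 20 libraries. The design written before the data were examined gave a count test for counts and this test for normalized values. Differences and fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. The 6 comparisons were KO against WT in females, KO against WT in males, the mean of both KO effects, the KO effect in males minus that in females, and males against females within WT and within KO. Adjusted p-values of genes are limma's. Fmr1 was also tested within each sex with an exact two-sided permutation test of the difference of mean log2 values over all 252 splits of 10 libraries.

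Lists of genes for pathways, synaptic functions and cell types were fixed before the data were examined. The 37 lists with at least 5 measured members were tested with camera (limma, preset inter-gene correlation 0.01), adjusted over the lists within each comparison. Camera with an estimated correlation and fry (limma) were alternatives. Fry tests whether the genes of a list move on balance to 1 side, and does not compare them with other genes. Of all list calls, only that of the X genes escaping inactivation was kept with an estimated correlation, in both comparisons of males with females. For each list the number of members past the threshold is given over all tested genes and adjusted over the list alone.

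Genes are named by a rule written before the data were examined. It takes Fmr1 and its family, then the 10 largest changes in each direction among genes past the threshold with a plain symbol and a group mean of at least 1 FPKM. Where fewer than 5 genes passed in a direction it takes the 5 smallest p-values there. From each list described it takes the members with the smallest p-values, and for the sexes the Y-linked genes and the X genes escaping inactivation. Names outside the rule are marked where they occur. Results of some list members are not reported here.

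The same fit was run on simulated values for the 13174 genes in the comparison of female KO with female WT, with 50 genes changed at each of 4 sizes. It recovered 46% of genes changed by a log2 of 0.25, 78% at 0.5, 94% at 1 and 100% at 2. Of its 166 calls, 7 were unchanged genes (4.22%), and it made 0 calls with limma among males, where nothing was changed. The simulated noise was drawn independently for each gene, without correlation between genes or a trend on GC content. These rates therefore need not hold for the real libraries.

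Alternatives planned before the data were examined were upper-quartile rescaling, robust empirical Bayes, no filter or a filter of 2 FPKM, a pseudocount of 0.1, a fit of only the compared groups, library weights, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were the removal of a smooth trend on GC content (loess, span 0.5, degree 1), leaving out the 4 libraries with Ttr above 500 FPKM, leaving out the 3 libraries with Prl above 4 FPKM, and Ttr and Prl as covariates, as well as the list tests with upper-quartile rescaling and the smaller pseudocount. The 3 Prl libraries are all female KO, so leaving them out also takes away 3 of the 5 libraries of that group. Random draws used fixed seeds. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9.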

Results

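Hippocampal gene expression was measured by RNA sequencing in Fmr1 KO and C57 (WT) mice of both sexes, with 5 libraries in each of 4 groups. Fmr1 encodes FMRP, an RNA-binding protein of neurons whose loss in humans causes fragile X syndrome. The series title names differences between the sexes as its subject, so the KO effect was compared within each sex and then between the sexes. Each library gave FPKM values for 13256 protein-coding genes. Between 12766 and 12899 genes reached 0.5 FPKM, and pairs of libraries correlated across genes at 0.977 to 0.990 (Pearson, log2). Mitochondrially encoded genes made up 17.5% to 20.4% of the summed FPKM. Sequencing depth is unknown, because the values are not counts.

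Fmr1 (ENSMUSG00000000838.17, mm10, chromosome X, 68678541 to 68717963) was low in every library labelled KO. In females it averaged 10.6 ± 0.558 FPKM in WT and 3.32 ± 0.327 in KO (SD, n = 5 each, exact permutation p = 0.0079, the smallest this design can give). In males the levels were 11.3 ± 0.527 and 3.56 ± 0.187 FPKM, with the same exact permutation p of 0.0079 (n = 5 each). KO libraries kept 31.2% of the WT level in females and 31.3% in males, which carry a single X chromosome. The highest KO value was 3.66 in females and 3.72 in males, against lowest WT values of 9.85 and 10.5. No other member of the FMRP family list (Fxr1, Fxr2, Aff2, Cyfip1, Cyfip2, Nufip1, Caprin1, G3bp1) passed the threshold in any comparison. Of these, Cyfip1, an FMRP partner in the WAVE actin complex, had a log2 difference of -0.14 in females (adjusted p = 0.0685) and -0.03 in males (adjusted p = 0.900).

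**Figure D1:**
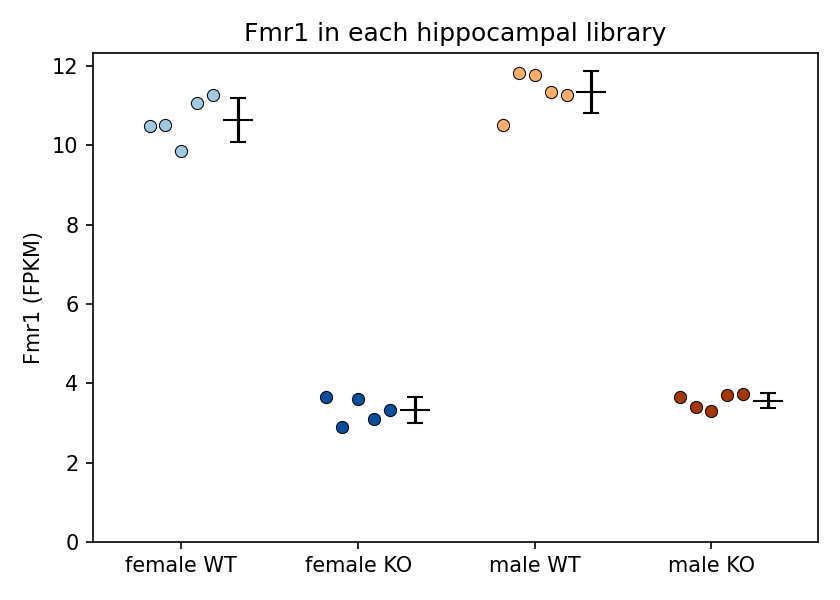
Fmr1 level in FPKM (vertical axis) in each of the 20 libraries, by group; points are libraries and the bar beside them is the mean ± SD of 5. All KO libraries lie between 2.90 and 3.72 FPKM and all WT libraries between 9.85 and 11.8.

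In the female hippocampus, Foxo6, a forkhead transcription factor, rose from 4.85 ± 0.63 FPKM in WT to 8.05 ± 0.851 in KO (SD, n = 5, log2 0.63, adjusted p = 0.000563). The inward-rectifier potassium channel gene Kcnj2 fell from 2.98 ± 0.581 to 1.60 ± 0.314 FPKM (log2 -0.61, adjusted p = 0.00293). The synaptotagmin gene Syt16 fell from 8.05 ± 0.404 to 5.33 ± 0.344 FPKM, and Serpina3n, a protease inhibitor made by reactive astrocytes, from 22.3 ± 2.18 to 16.2 ± 1.06 (both chosen after their values were seen). The largest rise among named genes was that of Fbxo33, a substrate receptor of ubiquitin ligases, from 2.97 ± 0.663 to 11.4 ± 0.688 FPKM. The collagen gene Col1a1 rose by a log2 of 0.54, the collagen chaperone gene Serpinh1 by 0.56 and the small heat shock protein gene Hspb1 by 0.56.

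Other genes that rose in female KO were Hist2h3c1 (log2 0.85), Taf13 (0.80), Nnat (0.60), the neuropeptide gene Cort (0.57) and Mfsd2a (0.54), a lipid transporter of the blood-brain barrier. Cacna2d1, an auxiliary calcium channel subunit (log2 -1.10), Zfp451 (-1.04), Tprkb (-1.04) and the kinase gene Camkk1 (-0.94) fell. So did Ppp1r9a, which encodes the actin-binding protein neurabin (-0.73), Rpa1, a subunit of a single-strand DNA-binding complex (-0.72), the myosin gene Myo6 (-0.60) and the keratin gene Krt9 (-0.55). Hist2h3c1, Taf13, Zfp451, Ppp1r9a and Rpa1 stood at 2 separate levels over the 20 libraries, with a gap between them of over 50% of their range. In all, 438 of 13174 genes passed in females (limma), 237 higher and 201 lower in KO, and 2573 had an unadjusted p under 0.05. The higher share of 54.1% became 43.6% with upper-quartile rescaling and 43.3% after removal of the GC trend. Higher genes had a median GC content of 55.7% and lower genes 45.4%, against 50.8% for all tested genes, and the 5 female KO libraries had the 5 steepest positive slopes of expression on GC content. The prolactin gene Prl, a pituitary hormone, was above 4 FPKM in 3 female KO libraries and in no other, and the choroid plexus gene Ttr was above 500 FPKM in female WT replicate 4, female KO replicates 4 and 5 and male KO replicate 2. Without the 3 libraries 8 genes passed, without the 4 libraries 76, with both genes as covariates 39, after removal of the GC trend 240, and in a fit of only the compared groups 91. The 3 Prl libraries are 3 of the 5 in female KO, and the other ways of leaving out 3 of these gave 3 to 156 calls (median 40). Since Prl was above 4 FPKM only in female KO, it overlaps that group as a covariate. Leaving out single libraries gave 176 to 455 calls, and the lowest counts came without WT replicate 4 (176), 3 (211) or 5 (217) and without KO replicate 3 (180), 2 (208) or 5 (258).

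**Figure D2:**
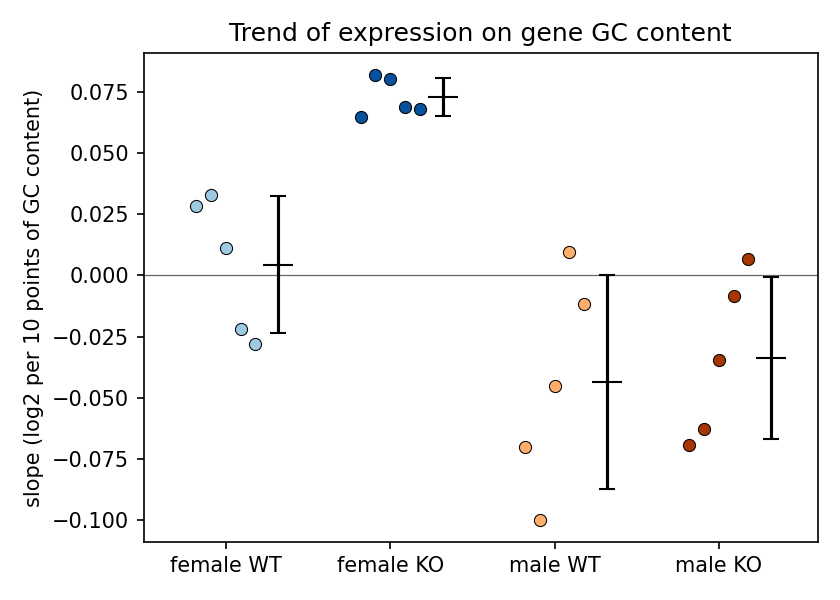
Slope of log2 expression on gene GC content in each library (log2 per 10 points of GC, relative to the mean of all libraries), by group, with mean ± SD of 5. Female KO libraries lie between 0.0648 and 0.0818, above all other libraries.

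As groups, markers of dentate granule cells were lower in female KO, with all 10 measured members below 0 (median log2 -0.21). The channel gene Trpc6 (log2 -0.27) and Tdo2, a tryptophan dioxygenase (-0.31), fell, while Dsp had -0.45 (adjusted p = 0.0534). Over all tested genes 2 of the 10 passed, and 7 when adjusted over the list alone (camera adjusted p = 3.11e-05; adjusted p = 0.275 with an estimated correlation). Genes of heat shock and protein folding were higher (25 measured, median 0.11): the endoplasmic reticulum chaperone Calr rose by 0.24, Pdia4 by 0.32, Dnajb1 by 0.27 and Hspb1 by 0.56. These were the 4 that passed, against 5 adjusted over the list alone (camera adjusted p = 0.000177; adjusted p = 0.275 with an estimated correlation). Immediate early genes, which respond to neuronal activity, were higher on balance (33 measured, median 0.13) but split. Fosl2 (0.40), Dusp5 (0.26) and Homer1 (0.49) rose while Ptgs2 (-0.38) and Bdnf (-0.26) fell, and 10 passed adjusted over the list alone (camera adjusted p = 0.0233; adjusted p = 0.410 with an estimated correlation). This list call also ended after removal of the GC trend and without the 4 Ttr libraries.

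Of the synaptic and channel lists, 3 were slightly lower in female KO and passed, while those of GABA synapse and presynaptic vesicle genes did not pass. Of 54 mRNAs bound by FMRP at synapses (median -0.05), Nrxn3 (-0.18), Grin2a (-0.23), Grin2b (-0.20) and Cacna1e (-0.18) fell and Nlgn2 rose, with 6 adjusted over the list alone (camera adjusted p = 0.0321; adjusted p = 0.512 with an estimated correlation). Of 47 excitatory synapse genes (median -0.03), Grin2a, Grin2b and Nlgn1 (-0.19) fell and Homer1 rose, with 5 adjusted over the list alone (camera adjusted p = 0.0233; adjusted p = 0.410 with an estimated correlation). Of 36 voltage-gated channel genes (median -0.05), Kcna4 (-0.46), Kcnq3 (-0.27), Cacna2d1 and Cacna1e fell and none rose, with 5 adjusted over the list alone (camera adjusted p = 0.0321; adjusted p = 0.425 with an estimated correlation). Markers of CA3 and CA2 pyramidal cells had a median of -0.13 over 11 genes, of which 0 passed with limma over all genes and 4 adjusted over the list alone (camera adjusted p = 0.0236; adjusted p = 0.275 with an estimated correlation). The 2 with the smallest p were Pcp4 (-0.15, adjusted p = 0.115) and Cpne4 (-0.13, adjusted p = 0.123). The FMRP-bound and excitatory synapse calls ended without the 3 Prl libraries, the FMRP-bound and channel calls without the 4 Ttr libraries, and all 3 with Ttr and Prl as covariates. Single libraries also ended them: FMRP-bound without WT replicate 1 or 3 or KO replicate 4 or 5, excitatory synapse without WT 3 or 5, and channels without WT 1, 3 or 5 or KO 5. In the FMRP family list Fmr1 itself was the only member past the threshold (camera adjusted p = 0.0185; adjusted p = 0.275 with an estimated correlation).

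Markers of vessel walls, meninges, blood and the ventricle lining were higher in female KO. In this group Ttr reached 1097 and 1461 FPKM in replicates 4 and 5 and Prl 42.2 FPKM in replicate 3. Ttr was also at 878 FPKM in female WT replicate 4, and the choroid plexus list did not pass. The hemoglobin gene Hbb-bs did not follow Ttr in female KO: it was at 246.5 and 157 FPKM in replicates 4 and 5 and at 229 in replicate 1 (Ttr 37.4). Meningeal fibroblast genes had a median of 0.48 over 9 genes, of which Col1a1 passed and 2 passed adjusted over the list alone (camera adjusted p = 0.00153; adjusted p = 0.410 with an estimated correlation). Col1a2 had 0.38 (adjusted p = 0.0688). Hemoglobin and other erythrocyte genes had a median of 0.47 over 5 genes, with 4 adjusted over the list alone (camera adjusted p = 0.00736; adjusted p = 0.410 with an estimated correlation). Hba-a1 had 0.52 (adjusted p = 0.0904) and Hbb-bs 0.48 (adjusted p = 0.115). Pericyte and smooth muscle genes had a median of 0.21 over 8 genes, with 5 adjusted over the list alone (camera adjusted p = 0.00736; adjusted p = 0.410 with an estimated correlation), and ependymal genes a median of 0.27 over 9 (camera adjusted p = 0.0233; adjusted p = 0.410 with an estimated correlation). The contractile gene Acta2 had 0.74 (adjusted p = 0.086) and the axonemal gene Ak7 0.30 (adjusted p = 0.241). Oligodendrocyte markers were lower, all 10 below 0 (median -0.16), and of these Opalin (-0.47) fell, also adjusted over the list alone (camera adjusted p = 0.00898; adjusted p = 0.496 with an estimated correlation). Nuclear genes of oxidative phosphorylation (72 measured, median 0.08) and cytosolic ribosomal protein genes (77 measured, median 0.06) were slightly higher, with Cyc1 (0.23), Atp5g1 (0.24) and Rpl29 (0.30) the members past the threshold, 2 and 1 also adjusted over each list alone (camera adjusted p = 0.00024 and 0.00261; adjusted p = 0.546 and 0.622 with an estimated correlation). Of the 15 list calls in females, 8 up and 7 down, 7 were lost without at least 1 single library. These were oligodendrocytes (WT replicate 1 or 4), immediate early genes (WT 4 or 5, KO 1), ependymal cells (WT 5) and CA3 and CA2 cells (KO 4), besides the 3 synaptic and channel lists. The meningeal, erythrocyte, pericyte, ribosomal protein, CA3 and CA2 and FMRP family calls ended without the 3 Prl libraries and also with Ttr and Prl as covariates. Without the 4 Ttr libraries the pericyte, oligodendrocyte, oxidative phosphorylation, ribosomal protein, CA3 and CA2 and FMRP family calls ended.

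**Figure D3:**
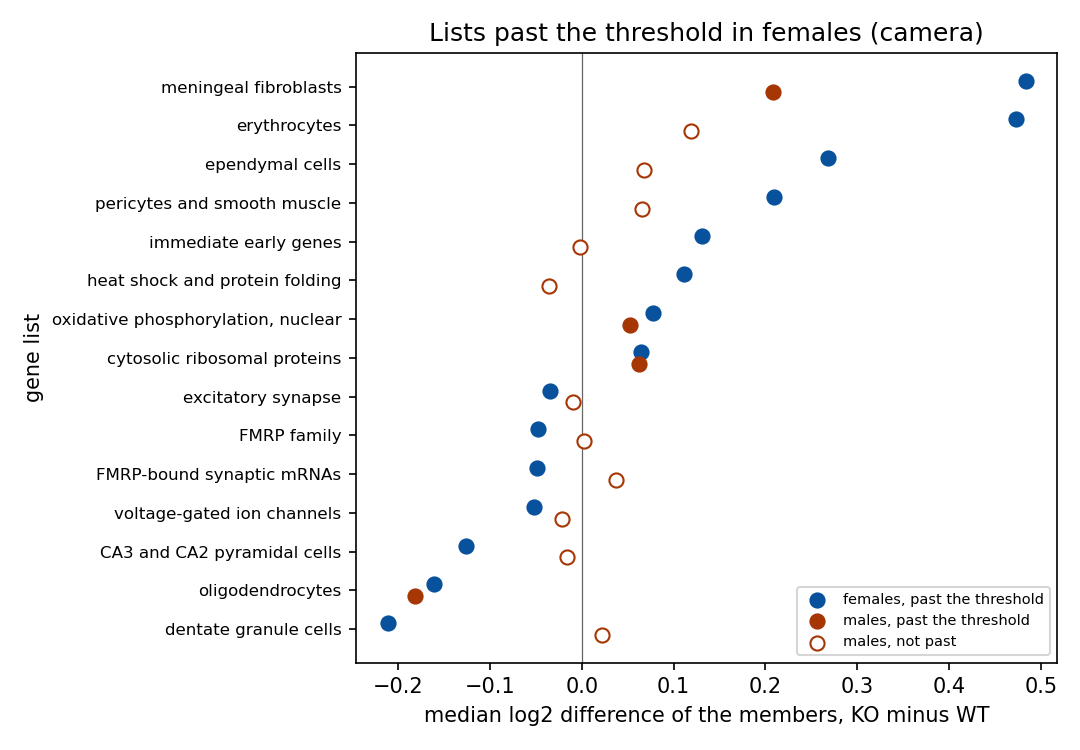
Median log2 difference of list members, KO minus WT (horizontal axis), in females and in males, for the 15 lists past the camera threshold in females; filled points passed, open points did not. Dentate granule cell markers lie at -0.21 in females and 0.02 in males, and oligodendrocyte markers at -0.16 and -0.18.

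In the male hippocampus the genes that differed were few, and all were lower in KO. Besides Fmr1, Serpina3n fell from 21.8 ± 1.26 to 15.2 ± 1.49 FPKM (SD, n = 5, log2 -0.49, adjusted p = 0.00172) and Syt16 from 8.77 ± 0.395 to 6.05 ± 0.829 (log2 -0.48, adjusted p = 0.00095). The other 3 genes, chosen after their values were seen, belong to skeletal muscle: Ckm, the muscle creatine kinase, was at 0.694 ± 0.236 FPKM in WT and listed at 0 in every KO library; Atp2a1, a calcium pump of fast muscle, was at 0.921 ± 0.297 and 0.0481 ± 0.0207; and the fast myosin gene Myh4 was at 0.875 ± 0.287 and 0.0901 ± 0.018. In female WT they were as low as in KO (Ckm 0, Atp2a1 0.0398 and Myh4 0.0785 FPKM). With limma 6 of 13174 genes passed, 0 higher and 6 lower, and 1145 had an unadjusted p under 0.05. The 5 higher genes with the smallest p did not pass: Fam206a (log2 0.22, adjusted p = 0.106), Pigs (0.19, 0.106), Capn5 (0.20, 0.148), Zfp968 (0.48, 0.148) and the matrix gene Tnxb (0.26, 0.148). Stricter filtering at 2 FPKM, which removes the muscle genes, left 3 calls. Without WT replicate 3, 10 genes passed, 2 of them higher, and without WT replicate 1, 7 passed, 1 of them higher. Without WT replicate 2, 11 passed, and without the 4 Ttr libraries 12, all of them lower.

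Gene lists in males gave 7 calls, of which 0 were kept with camera without each single library. Of 100 splits of the male libraries, the real one among them, 21 gave at least 7 list calls. Oligodendrocyte markers were lower (median -0.18, all 10 below 0; camera adjusted p = 0.00171; adjusted p = 0.766 with an estimated correlation), with Opalin at -0.22 (adjusted p = 0.572), and the call ended without WT replicate 1. CA1 pyramidal markers had a median of -0.15 over 7 genes, with 3 adjusted over the list alone (camera adjusted p = 0.0475; adjusted p = 0.224 with an estimated correlation), among them Wfs1 (-0.35, adjusted p = 0.318). Extracellular matrix genes had a median of 0.05 over 25, with 2 adjusted over the list alone, and meningeal fibroblast genes 0.21 over 9, with 1 (camera adjusted p = 0.0183 and 0.0209; adjusted p = 0.224 and 0.766 with an estimated correlation). In both lists Col1a1 had the smallest p (0.35, adjusted p = 0.157). Astrocyte markers had a median of 0.06 over 10 genes, with 3 adjusted over the list alone (camera adjusted p = 0.0471; adjusted p = 0.224 with an estimated correlation), and the glutamate transporter Slc1a2 led them (0.17, adjusted p = 0.224). Ribosomal protein genes (median 0.06) and oxidative phosphorylation genes (0.05) passed without a member past the threshold (camera adjusted p = 0.000105 and 0.000423; adjusted p = 0.890 and 0.890 with an estimated correlation). Without male WT replicate 3 these medians became -0.0165 and -0.0075, and without male KO replicate 3 only 1 list passed. The matrix call also ended without WT replicate 1 or 4, the oxidative phosphorylation call without KO 5 and the meningeal call without WT 1, 3 or 5 or KO 1 or 2. Astrocytes ended without WT 1, 3 or 4 or KO 2 or 4, and CA1 cells without WT 1, 3, 4 or 5 or KO 1 or 2. The astrocyte, CA1 and meningeal calls ended without the 4 Ttr libraries, and astrocytes and CA1 cells with the covariates.

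Averaged over both sexes, Syt16 fell by 0.50 on the log2 scale (adjusted p = 5.5e-06), Krt9 by 0.49 (adjusted p = 0.00038) and, chosen after its value was seen, Serpina3n by 0.46 (adjusted p = 4.96e-05). Col1a1 rose by 0.45 (adjusted p = 0.00104), the neuropeptide gene Cort by 0.49 (adjusted p = 0.0085) and the lysosomal membrane gene Laptm4b by 0.71 (adjusted p = 0.0261). Fbxo33 (1.05), the receptor gene Gpr19 (0.45), Nnat (0.37) and Serpinh1 (0.33) also rose. In males Fbxo33 was uneven, at 3.51 ± 1.28 FPKM in WT and 6.61 ± 5.8 in KO (SD, n = 5), where it ran from 1.89 to 13.3. Tprkb (log2 -0.73), Zfp451 (-0.62), Zfp991 (-0.54), the nuclear matrix gene Banp (-0.53) and Pls3, an actin bundler (-0.50), also fell. Zfp451 stood at its lower level in 1 female WT, 5 female KO, 4 male WT and 5 male KO libraries, so its fall came mainly from females. With limma 424 genes passed, 182 higher and 242 lower, and 2373 had an unadjusted p under 0.05. Of these 228 were also among the 438 female calls, with which they share libraries. Fewer genes passed without the 4 Ttr libraries (181, of which 151 were among the 424), without the 3 Prl libraries (84, of which 77), with both genes as covariates (215, of which 181), and without female KO replicate 3 or male KO replicate 3 (273 each).

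Some calls of the mean effect lay side by side on a chromosome. On chromosome 2 between 175321955 and 177840336 (mm10), 15 of 29 tested genes passed and all 15 were higher, among them the zinc finger genes Zfp965 (log2 0.43), Zfp973 (0.42) and Zfp968 (0.35). Their summed level was 92.9 ± 3.85 FPKM in female WT, 136 ± 31.7 in female KO, 112 ± 16.6 in male WT and 160 ± 28 in male KO (SD, n = 5 each). Female KO replicate 4 lay at 85.7, below the lowest female WT library (87.5), and male KO replicates 4 and 5 lay at 131 and 129.5, below male WT replicate 5 (134). On chromosome 12 between 55080262 and 55263836, Fam177a (log2 -0.49), 1700047I17Rik2 (-0.50), Srp54b and both gene identifiers named Srp54a fell. Their sum was 80.7 ± 1.23 FPKM in female WT and 61.1 ± 12.4 in female KO, and 87.6 ± 1.52 in male WT and 66.6 ± 15.9 in male KO (SD, n = 5 each); male KO replicate 1 lay at 92.1. Many of these genes are near-identical copies, between which reads can be split arbitrarily. Within 10 Mb of Fmr1, 7 of 72 tested genes passed (Slitrk2, Cd99l2, Pnma3, Pnck, Dkc1, Fundc2 and Pls3), or 9.72%, against 416 of 13101 elsewhere, or 3.18%.

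**Figure D4:**
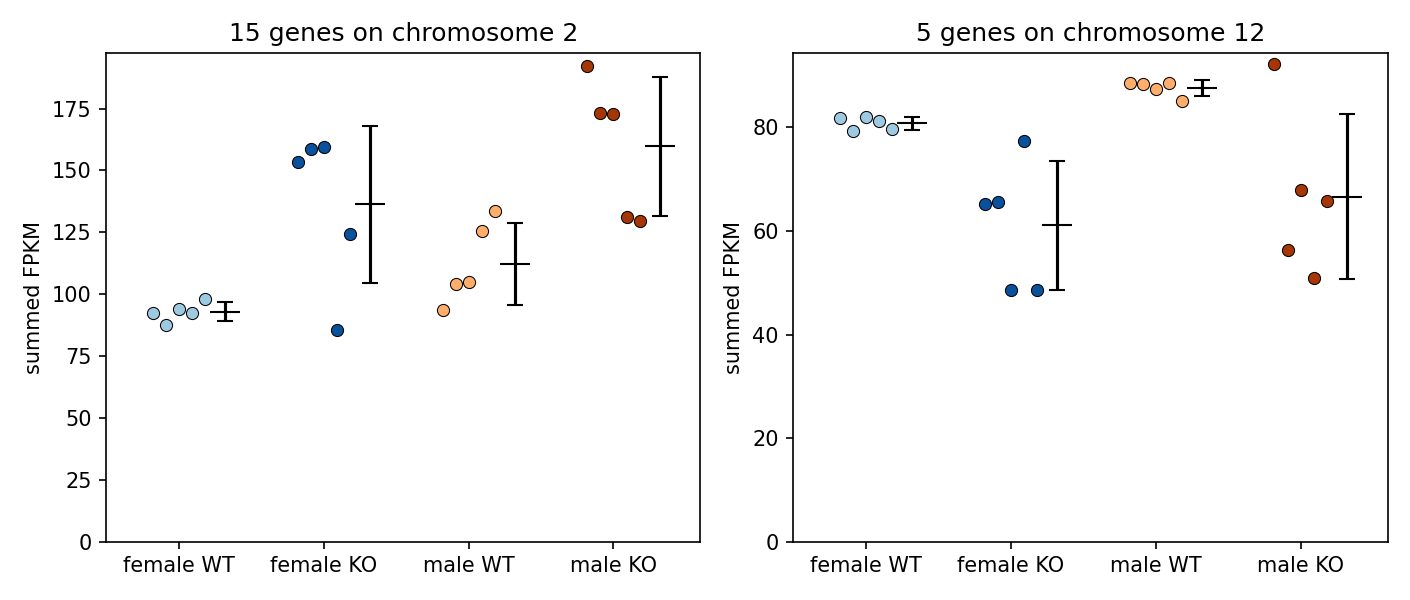
Summed FPKM of the 15 called genes on chromosome 2 (left) and of the 5 called genes on chromosome 12 (right) in each library, by group, with mean ± SD of 5. The KO libraries spread widely: on chromosome 12 from 48.5 to 92.1, against 79.2 to 88.5 in WT.

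Of the 37 lists, 13 passed for the mean effect, 9 up and 4 down. Extracellular matrix genes were higher (median 0.06 over 25), and of these Col1a1 and the perineuronal net gene Ncan (0.17) rose, with 6 adjusted over the list alone (camera adjusted p = 0.0119; adjusted p = 0.268 with an estimated correlation). Oligodendrocyte markers were lower, all 10 below 0 (median -0.17), and Opalin fell by 0.34 (camera adjusted p = 0.000297; adjusted p = 0.448 with an estimated correlation). Dentate granule cell markers had a median of -0.08, and Trpc6 (-0.17) fell (camera adjusted p = 0.00446; adjusted p = 0.448 with an estimated correlation). Calr was the member of the heat shock and protein folding list that rose (0.15; camera adjusted p = 0.0445; adjusted p = 0.448 with an estimated correlation). Atp5g1 (0.19), Atp5c1 (0.13) and Rpl29 (0.19) rose. The remaining calls were those of meningeal (median 0.29), erythrocyte (0.30), pericyte (0.11), ependymal (0.13), astrocyte (0.06), oxidative phosphorylation (0.06), ribosomal protein (0.06), CA3 and CA2 (-0.06) and FMRP family (-0.02) genes, with adjusted p between 0.268 and 0.558 with an estimated correlation. Of the 13 calls, 5 were lost without at least 1 single library. Heat shock and protein folding ended without female WT replicate 3, 4 or 5, female KO 1, 2 or 5, male WT 3 or 5 or male KO 2 or 3, and ependymal cells without female WT 5, female KO 5, male WT 3 or 5 or male KO 2, 3 or 4. Astrocytes ended without female WT 1, 3 or 4, female KO 3, 4 or 5, male WT 4 or male KO 2, 3 or 4, and with upper-quartile rescaling. CA3 and CA2 cells ended without female WT 5, female KO 4 or 5, male WT 3 or 5 or male KO 4, and the FMRP family without female KO 4. The Prl libraries, left out or as covariates with Ttr, ended the astrocyte, CA3 and CA2, FMRP family, pericyte and erythrocyte calls, and the covariates that of dentate granule cells. Without the 4 Ttr libraries the astrocyte, CA3 and CA2, FMRP family and pericyte calls ended.

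Across genes, the KO effects in both sexes correlated weakly (Pearson r = 0.166 over 13173 genes, which are not independent replicates). Of the 437 female calls other than Fmr1, 326 (74.6%) had the same sign in males, against 57.3% of all genes, and the median male effect was 0.223 of the female effect. These genes were chosen by their female values, which lowers this ratio by itself, so it does not measure the size of the male effect. Both sexes shared 3 calls (Fmr1, Serpina3n and Syt16), against 0.2 for independent lists of these sizes. Of these, Fmr1 was shared by design.

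**Figure D5:**
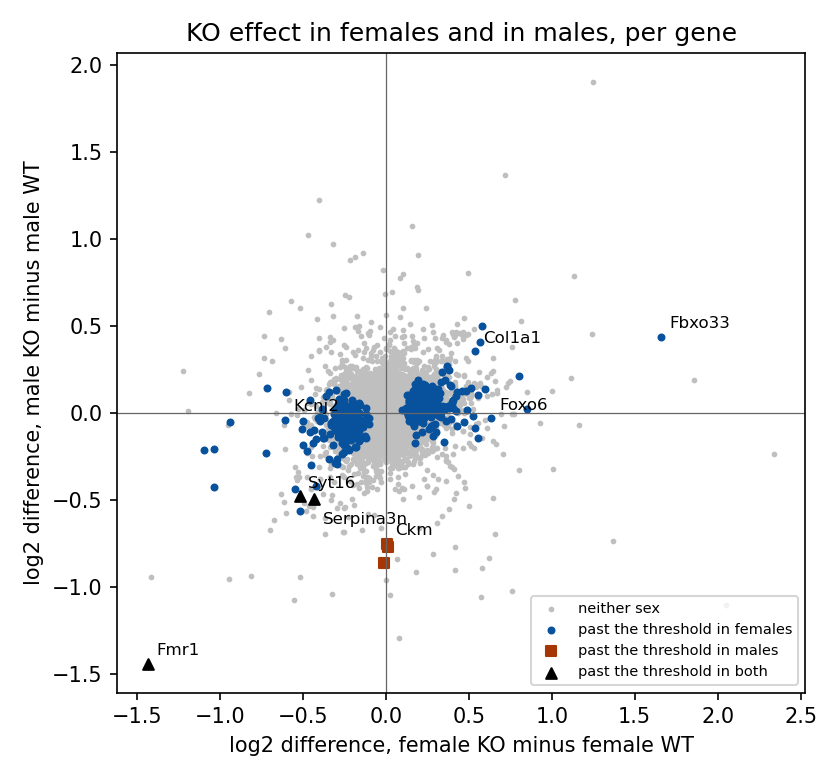
Log2 difference KO minus WT of each tested gene in females (horizontal axis) and males (vertical axis), marked by the sex in which it passed the threshold. Fmr1 lies at -1.43 and -1.44, and Foxo6 at 0.63 in females and -0.03 in males.

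The difference of the KO effect between the sexes was tested directly. Foxo6 rose in female KO but stood at 5.30 ± 0.54 FPKM in male WT and 5.15 ± 0.297 in male KO (SD, n = 5; difference of the effects -0.66, adjusted p = 0.0268). The ubiquitin ligase gene Fbxl14 (-0.31, adjusted p = 0.0436) and Emc1, part of a membrane insertion complex (-0.24, adjusted p = 0.0493), had lower effects in males as well. The other 3 calls were the muscle genes Ckm (-0.76), Atp2a1 (-0.85) and Myh4 (-0.78), chosen after their values were seen. With limma 6 genes passed, 0 higher and 6 lower, and 1320 had an unadjusted p under 0.05. Of the 6, 3 kept their call without each single library. The call of Foxo6 ended at a filter of 2 FPKM, which its levels pass (4.02 FPKM or more in every library). The higher effects in males with the smallest p did not pass: Rpa1 (0.86, adjusted p = 0.0677), the matrix protease gene Mmp16 (0.45, 0.196), Kcnj2 (0.57, 0.196), Nup93 (0.35, 0.196) and Cog5 (0.24, 0.196). At a filter of 2 FPKM 0 genes passed with limma, and 2 or 3 passed after removal of the GC trend, without the Prl libraries, with Ttr and Prl as covariates or without each of 9 single libraries (female WT replicate 3, female KO replicates 1, 4 and 5, male WT replicate 5, male KO replicates 1, 2, 3 and 5).

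As groups, heat shock and protein folding genes had a lower KO effect in males (median -0.19 over 25, 0 past with limma over all genes and 7 adjusted over the list alone; camera adjusted p = 4.03e-06; adjusted p = 0.208 with an estimated correlation), with Hspb1 at -0.70 (adjusted p = 0.194) and Dnajb1 at -0.29 (adjusted p = 0.269). Dentate granule cell markers had a higher effect in males (median 0.25, all 10 above 0; camera adjusted p = 1.19e-05; adjusted p = 0.260 with an estimated correlation), led by Tdo2 (0.31, adjusted p = 0.310). CA1 pyramidal markers were lower (median -0.21, 7 of 7 below 0; camera adjusted p = 0.00437; adjusted p = 0.105 with an estimated correlation), led by Pou3f1 (-0.33, adjusted p = 0.321). FMRP-bound synaptic mRNAs (median 0.06) and immediate early genes (-0.13) also passed (camera adjusted p = 0.00437 and 0.0231; adjusted p = 0.631 and 0.631 with an estimated correlation), with Cacna1e at 0.22 (adjusted p = 0.310) and Dusp5 at -0.35 (adjusted p = 0.252). The call of immediate early genes ended after removal of the GC trend, without the 4 Ttr libraries, and without female WT replicate 4 or 5, female KO 1 or 4, male WT 1 or male KO 4. That of FMRP-bound mRNAs ended without the 3 Prl libraries, with the covariates and without male KO 4, and that of CA1 cells without the 3 Prl libraries. Of 100 splits of the libraries, the real one among them, 72 gave at least 5 list calls. Because these splits mix the sexes within each genotype, they can carry the difference between the sexes into the contrast. They therefore cannot judge the real count of 5.

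Between WT males and WT females the genes of the sex chromosomes led. The Y-linked genes Ddx3y (14.1 ± 1.98 FPKM in male WT, 0.015 ± 0.0101 in female WT, SD, n = 5), Eif2s3y (13.6 ± 1.84 and 0.00629 ± 0.00875), Uty (log2 1.61) and Kdm5d (1.32) were higher in males, as the labels require. Their X-linked relatives Eif2s3x (27.5 ± 1.19 FPKM in males and 39.3 ± 1.92 in females, log2 -0.50, adjusted p = 5.64e-08) and Ddx3x (-0.24), and Pbdc1 (-0.22), were lower in males. X genes escaping inactivation passed as a list, with 3 of 7 past the threshold and 5 adjusted over the list alone (camera adjusted p = 1.23e-07; adjusted p = 0.000719 with an estimated correlation). Kdm6a had -0.34 (adjusted p = 0.0944), Kdm5c -0.30, Utp14a 0.07 and Mid1 0.20. Among autosomal genes, the skeletal actin gene Acta1 (0.54), Ccdc88a (0.27), Ankrd12 (0.26), Esf1 (0.25), Habp4 (0.22) and Ola1 (0.14) were higher in males and Nat8f5 (-0.65) lower. The muscle genes Atp2a1 (0.87, adjusted p = 6.3e-07), Ckm (0.75, adjusted p = 6.53e-07) and Myh4 (0.78, adjusted p = 2.95e-06), chosen after their values were seen, were also higher in WT males. With limma 17 genes passed, 13 higher and 4 lower, 1356 had an unadjusted p under 0.05, and Sema4c (-0.28, adjusted p = 0.0521) fell just short. In a fit of the 2 WT groups alone 9 genes passed, 8 of them among the 17, and Ddx3x, Pbdc1, Nat8f5, Acta1, Ccdc88a, Ankrd12, Esf1, Habp4 and Ola1 did not. Only 11 passed at 2 FPKM, without female WT replicate 3 or without male WT replicate 5.

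Other lists in WT were lower in males with little support from single genes. Of 100 splits of the WT libraries, the real one among them, 45 gave at least the 7 list calls found. Interferon response genes had a median of -0.14, with 23 of 24 below 0 (camera adjusted p = 2.48e-05; adjusted p = 0.792 with an estimated correlation), led by Gbp2 (-0.29, adjusted p = 0.346) and Isg15 (-0.42, adjusted p = 0.360). Oxidative phosphorylation (median -0.10), meningeal (-0.29), mitochondrially encoded (-0.05) and ribosomal protein genes (-0.06) were lower as well (camera adjusted p = 3.24e-08, 0.00387, 0.0151 and 0.000408, or adjusted p = 0.803, 0.792, 0.813 and 0.813 with an estimated correlation). Their members with the smallest p were Atp5k (-0.32, adjusted p = 0.186), Col1a1 (-0.34, adjusted p = 0.186), mt-Nd4l (-0.12) and Rpl5 (0.10). Rpl5 was higher in males, against the direction of its list. The ribosomal median became 0.0119 without male WT replicate 3. CA1 pyramidal markers were higher, 7 of 7 above 0 (median 0.14; camera adjusted p = 0.0154; adjusted p = 0.158 with an estimated correlation), led by Man1a (0.14, adjusted p = 0.395). The CA1 call ended without male WT replicate 4 or 5, the meningeal call without female WT 2, the ribosomal call without male WT 3 and the mitochondrial call without female WT 4 or male WT 2, 4 or 5.

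Between KO males and KO females, genes of protein folding were lower in males: Hspb1 stood at 2.50 ± 0.436 FPKM in males and 5.27 ± 0.783 in females (SD, n = 5, log2 -0.84, adjusted p = 0.000371), Calr differed by -0.27, Pdia6 by -0.31, Pdia4 by -0.35 and Sdf2l1 by -0.64. As a list, 9 of 25 were lower in males and 16 adjusted over the list alone (median -0.26; camera adjusted p = 7.85e-08; adjusted p = 0.097 with an estimated correlation). Foxo6 (-0.55), Nnat (-0.63), Hist2h3c1 (-0.82), the matrix gene Mgp (-0.70), Cd59a (-0.71), Ahdc1 (-0.60), Dap (-0.54) and Retreg3 (-1.07) were lower in males. Kcnj2 (0.54), Rpa1 (0.76), Myo6 (0.62), the actin regulator Abi2 (0.69), Usp49 (0.85) and Hsd11b1 (0.54), which regenerates glucocorticoids, were higher in males, as were the Y-linked genes Eif2s3y (15.1 ± 0.412 FPKM in males, 0.00841 ± 0.0115 in females), Ddx3y (log2 3.94), Uty (1.56) and Kdm5d (1.44). With limma 709 genes passed, 297 higher and 412 lower in males, and 3070 had an unadjusted p under 0.05. The higher share of 41.9% became 49.5% with upper-quartile rescaling and 51.5% after removal of the GC trend. The difference correlated with GC content across genes (Spearman rho = -0.480), and after removal of the GC trend 103 genes passed, without the 4 Ttr libraries 71, without the 3 Prl libraries 23 and with both as covariates 75. Single libraries also decided the count, which was 160 without male KO replicate 1, 253, 270, 357 and 447 without female KO replicates 3, 5, 2 and 4, and 333 and 353 without male KO replicates 2 and 4.

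The X escape list was again lower in KO males, with Eif2s3x (-0.46), Pbdc1 (-0.21) and Kdm6a (-0.26) past the threshold and Kdm5c (-0.37, adjusted p = 0.0598), Ddx3x (-0.11, adjusted p = 0.0624), Mid1 (-0.44, adjusted p = 0.189) and Utp14a (0.04, adjusted p = 0.529) not (6 adjusted over the list alone; camera adjusted p = 0.000105; adjusted p = 0.0113 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.12, and 6 of 72 were lower, among them Cyc1 (-0.34), Cox8a (-0.31), Ndufa2 (-0.31) and Atp5g1 (-0.24), with 15 adjusted over the list alone (camera adjusted p = 6.34e-07; adjusted p = 0.543 with an estimated correlation). Of 33 immediate early genes (median -0.16) Dusp5 (-0.34) and Jund (-0.33) were lower and Ptgs2 (0.27) higher, with 10 adjusted over the list alone (camera adjusted p = 0.000506; adjusted p = 0.429 with an estimated correlation). Tdo2 (0.30), Stxbp6 (0.28), Prox1 (0.28) and Dsp (0.44) were higher among 10 dentate granule markers, with 5 adjusted over the list alone (camera adjusted p = 0.00129; adjusted p = 0.429 with an estimated correlation). Col1a1 (-0.52) and Col1a2 (-0.40) were lower among 9 meningeal genes, with 4 adjusted over the list alone (camera adjusted p = 0.000454; adjusted p = 0.429 with an estimated correlation), again beside the high Ttr and Prl of some female KO libraries. Ribosomal protein genes had a median of -0.07 with 0 members past the threshold with limma (camera adjusted p = 0.00823; adjusted p = 0.789 with an estimated correlation). The ribosomal call ended without female KO replicate 4, male KO 1 or male KO 4, and without the 4 Ttr libraries. The ribosomal and meningeal calls ended without the 3 Prl libraries, and these and the dentate granule call with Ttr and Prl as covariates. Of 100 splits of the KO libraries, the real one among them, 47 gave at least the 7 list calls found.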

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

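Of the tests in this part, those of the GC trend, of the direction of the interaction calls and of the chromosome segments were chosen after the result was seen, while the tests of other-tissue RNA and of unseen muscle genes were prompted by the patterns but fixed before their own values were computed, as were the splits of the libraries.

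Some single values lay far from the rest of their group. Laptm4b was at 28.1 FPKM in female WT replicate 3 (nearest other library 16.7), 18.8 in female KO replicate 1 (35.3), 31.1 in male WT replicate 2 (16.5) and 16.3 in male KO replicate 3 (30.6). Ckm was at 0.029 FPKM in female KO replicate 1 and listed at 0 in the other 4. Myh4 was at 0.026 FPKM in female WT replicate 5 (nearest 0.084). Ddx3y was at 0.0161 FPKM in female KO replicate 5, with 0 in the other 4, and at 17.6 in male WT replicate 5 (nearest 13.5). The rule marks about 1 in 20 groups by chance, and it marked 8 of 72 groups over 18 genes (11.1%). All libraries were kept.

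The KO effect in males minus that in females passed for Ckm (-0.76), Atp2a1 (-0.85), Myh4 (-0.78), Foxo6 (-0.66), Fbxl14 (-0.31) and Emc1 (-0.24). As lists, heat shock and protein folding (median -0.19), dentate granule cells (0.25), FMRP-bound synaptic mRNAs (0.06), CA1 pyramidal cells (-0.21) and immediate early genes (-0.13) passed.

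The first pattern is the gap between 438 calls in females and 6 in males. After removal of a smooth trend on gene GC content 240 genes passed in females, 203 of them among the 438. That argues against this smooth trend as the whole cause, and only against it. Female KO slopes (0.0648 or more) lay apart from those of all other libraries (0.0327 or less). GC effects of another form therefore cannot be told apart from the group and stay open. RNA of pituitary and choroid plexus in some female KO libraries stays open: 8 genes passed without the 3 Prl libraries, and 2 of the 10 ways of leaving out 3 female KO libraries, this one among them, gave as few (others 3 to 156, median 40), but every way leaves out at least 1 Prl library, so none separates this RNA from the smaller n. A larger effect of the missing Fmr1 in females stays open too: only 3 of the 6 interaction calls (Foxo6, Fbxl14 and Emc1) had the larger effect in females, and 0 genes passed with limma at 2 FPKM. The other 3 calls were the muscle genes, which stood high only in male WT. With so few calls, already seen when the test was chosen, their direction cannot decide this. The labels do not give the zygosity of the female KO mice, but Fmr1 at 31.2% of WT in female KO, against 31.3% in male KO, argues against an intact copy in them.

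The second pattern is calls of the mean effect that lie together, which called genes placed at random do not give: 15 calls of the same direction fell within 3 Mb on chromosome 2, and the highest of 1000 draws had 9. The draws took genes as independent, while near-identical copies can share reads and pass together, so the 15 calls need not be separate changes. On chromosome 12, reads shared among near-identical copies as the whole cause stay open. All 4 KO libraries lowest in Srp54a and Srp54b were the 4 lowest in the other genes of the segment. Those other genes lie between the Srp54 copies and may share reads as well, so this test cannot decide. The KO libraries did not share a common lower level: their SD was at least 10.1 times that among WT, and male KO replicate 1 lay at 92.1 FPKM. The exact permutation p was 0.00876 over both sexes, a test added after p = 0.159 in females and 0.0873 in males were seen. This spread was known before its test was chosen, so the p-value adds no independent evidence against a shift of the same size in every KO animal. A copy number that may differ among the KO animals stays open: 5 of 5 genes varied more than each of the 10 nearest tested genes, but this restates a spread already seen. Near Fmr1, DNA of another strain carried along with the knockout allele could account for the share of calls (Fisher exact p = 0.0082), and sequence variants in the reads were not analysed here.

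The third pattern is that skeletal muscle genes were lower in male KO than in male WT, where male WT stands apart: female WT, with Fmr1 present, had 0 FPKM of Ckm, 0.0398 of Atp2a1 and 0.0785 of Myh4. RNA of skeletal muscle in the male WT libraries is a candidate explanation that stays open: 8 of 35 muscle genes not looked at before were measured, with a median log2 difference of -0.0927, 7 of them below 0 and 0 past the threshold with limma. Between WT males and WT females the same 8 genes went both ways, from -0.18 (Cox7a1) to 0.07 (Tnni1), without a member past the threshold. The brain expresses many of these genes, which dilutes such a test. An effect of Fmr1 on these genes that is limited to males was not tested separately.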

How the results depend on the processing

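Removal of the GC trend, leaving out the Ttr or the Prl libraries, and Ttr and Prl as covariates were chosen after the data were seen, as were the list tests under upper-quartile rescaling and the smaller pseudocount, and all other alternatives were planned. With an estimated correlation the list calls became 0 in females, 0 in males, 0 for the mean effect, 0 for the difference of the effects, 1 between the sexes in WT and 1 in KO. Fry gave 11 lists in females, 6 of them among the 15, 1 list in males that was not among the 7, 5 for the mean effect, 2 for the difference and 1 in WT. In KO fry gave 7 lists, 5 of them among the 7 camera calls, without those of oxidative phosphorylation and ribosomal protein genes. A filter of 2 FPKM gave 3 genes in males, 0 for the difference and 11 between the sexes in WT, and a fit of only the compared groups gave 91 in females and 9 in WT. The replicate block gave 3 genes for the difference; replicate numbers do not pair the groups, since correlations between libraries of equal number ran from -0.105 to 0.0651 over 30 pairs and the own number was best in 5. GC removal gave 240 genes in females, 3 for the difference and 103 in KO, with 16 lists in KO. Without the 4 Ttr libraries 76 genes and 7 lists passed in females, 12 genes in males, 181 genes for the mean effect, 11 lists for the difference and 71 genes in KO. Without the 3 Prl libraries 8 genes and 8 lists passed in females, 84 genes for the mean effect, 2 genes and 3 lists for the difference and 23 genes in KO. With Ttr and Prl as covariates 39 genes and 7 lists passed in females, 215 genes and 7 lists for the mean effect, 3 genes for the difference, and 75 genes and 4 lists in KO. Leaving out each library in turn gave 176 to 455 genes and 12 to 19 lists in females, 6 to 11 and 1 to 8 in males, 273 to 449 and 9 to 15 for the mean effect, 3 to 7 and 3 to 9 for the difference, 11 to 17 and 5 to 8 in WT, and 160 to 692 and 6 to 17 in KO. Without male WT replicate 3 medians changed sign: oxidative phosphorylation genes in males to -0.0075 (range over single libraries -0.0075 to 0.1004), ribosomal protein genes in males to -0.0165 (to 0.095) and ribosomal protein genes between the sexes in WT to 0.0119 (from -0.0944). The cause of these moves was not tested. Of 43 named calls in females 4 were kept under every alternative, 39 ended without the Prl libraries and 17 without at least 1 single library. Kept under every alternative were 5 of 6 in males, 10 of 28 for the mean effect, 2 of 6 for the difference, 8 of 17 in WT and 11 of 39 in KO, and 0 of the 139 changed direction.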

Other observations

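Some neuronal lists did not pass in females although single members did. Among GABA synapse genes (median log2 -0.01), Gphn (-0.17) and Gabra4 (-0.27) fell while Nlgn2 (0.23) rose, with 8 adjusted over the list alone (camera adjusted p = 0.382). Among presynaptic vesicle genes (median 0.01), Syp (0.19) and Vamp2 (0.14) rose and Nrxn3 (-0.18) fell (camera adjusted p = 0.562). Among autism risk genes (median -0.03), Cul3 (-0.17) and Grin2b (-0.20) fell (camera adjusted p = 0.0578). Microglia markers had a median of -0.02 with 0 past the threshold with limma (camera adjusted p = 0.491).

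Of the tests in this part, the splits of the libraries were planned, and those after GC removal and the search for genes at 2 levels were chosen after the result was seen.

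For each comparison the libraries were split 100 ways, the real grouping among them. As many genes as in the real grouping passed in 1 split in females (438, highest other 3), 1 in males (6, highest other 2), 1 for the mean effect (424, highest other 3), 3 for the difference of the effects (6, highest other 23), 1 between the sexes in WT (17, highest other 2) and 1 in KO (709, highest other 6). For lists the numbers were 4 in females (15, highest other 20), 21 in males (7, highest other 10), 3 for the mean effect (13, highest other 16), 72 for the difference (5, highest other 15), 45 in WT (7, highest other 16) and 47 in KO (7, highest other 19). The other splits gave a median of 4 lists in males and of 6 in each other comparison. In males, for the difference, in WT and in KO, list counts like the real ones were thus common among other splits. In the splits of the difference by sex, 2 others gave 23 and 15 genes. These splits exchanged the sexes within WT and within KO separately, so unequal mixes can carry the difference between the sexes into the contrast. They are therefore not a reference without an effect, and the gene and list counts of the difference cannot be judged by them. After GC removal it was 1 split in females (240, highest other 5), 1 for the mean effect (322, highest other 3) and 1 in KO (103, highest other 3).

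Of 13174 tested genes, 184 stood at 2 separate levels. Rpa1 was at a mean of 6.57 FPKM in 6 libraries, all 5 female KO and 1 male WT, and at 11.8 in the others. Retreg3 was at 3.22 FPKM in 3 male KO libraries and 13.6 elsewhere, and Zfp451 at 1.39 in 15 libraries and 4.56 in the others. The cause was not tested.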
